A study of Mus musculus with 6 samples.

How the data were processed

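RNA was taken from hearts of C57BL/6 mice, and 6 libraries were made, 3 labelled as Usp13 knockout and 3 as wild type. All 6 labels give TAC as the treatment, the usual abbreviation of transverse aortic constriction, a surgical narrowing of the aorta that loads the left ventricle with pressure. The series' design text instead speaks of mice given angiotensin II. The sample labels were followed, and the groups are called KO-TAC and WT-TAC. The labels describe no sham-operated group, so the effect of the operation itself was not analysed here. Per the labels' protocols, poly(A) RNA was selected from total RNA, fragmented, reverse transcribed and sequenced in paired ends on an Illumina NovaSeq instrument. The same protocol text mentions adipose tissue, while the source of every sample is given as heart.

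The deposited values are whole-number read counts per Ensembl gene, with 1 column per library and no scaling. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used, with no role or order stated for any of them. The same notes name the genome build mm8. The step that turned alignments into counts, the annotation release and the strand setting are not given in the sources used here. Of 55401 gene IDs in the table, 55141 matched a symbol in a GENCODE annotation of a later mouse assembly, and 260 kept their ID as a name. Because that assembly and the build in the notes differ, no gene positions are printed. Where 2 IDs share a symbol, the ID with the higher total count was used. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Genes with near-identical copies, among them the MHC class I genes of the H2-Q, H2-T, H2-K and H2-D groups, Apol9a and Apol9b, the globin genes, and Hspa1a and Hspa1b, have counts that depend on how shared reads were assigned, and their values are uncertain to that extent.

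Depth was 69010859 to 77950439 counts per library, and 21390 to 22979 genes had at least 1 count. Mitochondrially encoded genes took 26.1% to 33.1% of the counts. At this depth the spread between libraries, not counting error, set the precision, and the common biological coefficient of variation was 0.324. Every pair of libraries within a group differed far beyond sampling noise, with a mean chi-square per gene of 121.6 or more, so no library was treated as a repeat of another. The labels do not state that the replicates came from separate animals, and p-values measure the spread between these samples.

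Genes with low counts were removed with filterByExpr (minimum count 10), which left 17742 genes, 14520 of them protein coding. Library sizes were scaled with TMM factors. The 2 groups were compared with the edgeR 4.0.16 quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest), with group as the only term and Benjamini-Hochberg adjustment over all genes tested at 0.05. The standard error of a log2 fold change was approximated from its F statistic. Fold changes are KO-TAC over WT-TAC. CPM values were computed from the deposited counts with TMM-scaled library sizes, and means are given ± SD over 3 libraries. Computations ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with matplotlib 3.10.9.

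Before the data were examined, 39 gene lists were fixed, holding 989 symbols, of which 985 were in the table. The 38 lists with 5 or more genes tested entered limma's camera test on log2 CPM (prior count 2) with the inter-gene correlation preset at 0.01, adjusted over the 38 lists at 0.05. Camera with a correlation estimated for each list, and fry, were run beside it. Fry tests whether a list's genes move on balance in 1 direction and makes no comparison with other genes. Members were also counted past 0.05 when adjusted over the list alone. A library's list mean is the mean log2 CPM of the list's genes minus the mean of the WT-TAC libraries.

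The rule for named genes was also fixed before the data were examined. It takes Usp13, a panel of 11 genes, up to 4 members of each list with the smallest p, and the 12 genes in each direction with the smallest p among those past the threshold with separated groups and a mean CPM of 1 or more. If no gene passed, the 6 with the smallest p in each direction were to be named as not having passed, and this case applied. Symbols of the kinds Gm plus digits, Rik, LOC, MSTRG, ENSMUSG and pseudogenes ending in -ps were left out of the 6 in each direction by that rule, and other provisional symbols such as AW011738 were kept.

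The alternatives set beforehand were RLE and upper-quartile factors, DESeq2, limma voom with quality weights, no filter on low counts, a filter of 1 CPM in 3 libraries, each library left out in turn, the replicate number as a block, removal of mitochondrially encoded and globin genes, an added fold-change threshold, estimated correlations and fry. A fit on protein-coding genes and the number of interferon list members past 0.05 under each setting were chosen after seeing the data. Where the alternative settings that called a list are counted, estimated correlations and fry, which called 0 lists, are not among them. The shared replicate numbers are not said to mark a litter, batch or day.

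The gene tests, and camera with the preset correlation, were tested on simulated data with the real means and library sizes, in 3 draws with 200 changed genes each. Fry and camera with an estimated correlation were not. Changed genes were taken from those with a mean CPM of 1 or more. Counts were drawn independently for each gene, so variation shared by many genes between libraries was absent. The shares below need not hold for the real libraries. EdgeR recovered 36.7% of genes changed 2-fold, 88% changed 4-fold and 97.3% changed 8-fold, with 8.06% of its calls false. DESeq2 recovered 67.3% of genes changed 2-fold and 93.3% changed 4-fold, with 29.2% of its calls false. Limma voom recovered 34.7% and 82.7% at these sizes, with 7.02% of its calls false. Camera with the preset correlation gave unadjusted p of 1.44e-15 or less for 30 genes all raised 1.5-fold, and 0.277 to 0.803 for 30 unchanged genes. Since genes were drawn independently, this does not test how camera acts on lists whose genes vary together.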

Results

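Gene expression was measured by RNA sequencing in 6 libraries of mouse heart, 3 labelled as Usp13 knockout (KO-TAC) and 3 as wild type (WT-TAC), all under TAC. Usp13 encodes a deubiquitinase, an enzyme that removes ubiquitin from proteins. The comparison asks how loss of Usp13 alters the transcriptome of the pressure-loaded heart, the subject given by the series' title. Total counts were 72494509, 71174409 and 70980964 in KO-TAC 1 to 3 and 69010859, 70519297 and 77950439 in WT-TAC 1 to 3.

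Usp13 itself (ENSMUSG00000056900) was not lower in the libraries labelled KO-TAC. Its level was 201.3, 252 and 224 CPM in KO-TAC 1 to 3 and 209, 164 and 195 CPM in WT-TAC 1 to 3. The group means were 226 ± 25.5 and 189 ± 22.9 CPM (SD, n = 3 each). The log2 fold change was 0.25 ± 0.16 (SE), with a 95% interval from −0.11 to 0.61, and did not pass the edgeR test (unadjusted p = 0.142). The counts cover the whole gene and cannot show whether part of it was deleted. The genotype therefore rests on the labels alone, and every direction below is between libraries by label. Genes next to Usp13 on the chromosome were also close to equal in both groups, with a median log2 fold change of −0.08 over 13 genes (limma camera, adjusted p = 0.377). Mrpl47, a mitochondrial ribosomal protein gene among them, had a log2 fold change of −0.40 ± 0.18.

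The genes with the smallest p in the libraries labelled KO-TAC included contractile, MHC class I and receptor signalling genes, and none of them passed the edgeR test over all genes. Myh7, the slow beta-myosin heavy chain that is re-expressed in loaded mouse ventricle, stood at 1999 ± 614 CPM against 678 ± 122 CPM in WT-TAC (SD, n = 3 each), a 2.95-fold difference with a log2 fold change of 1.56 ± 0.28 (SE). H2-Q7 and H2-T22, nonclassical MHC class I genes, had log2 fold changes of 1.27 ± 0.25 and 0.76 ± 0.15. Apol9b, an apolipoprotein L gene, stood at 3.30 ± 0.62 against 0.78 ± 0.34 CPM (log2 2.08 ± 0.40). Dok7, an adaptor of the muscle-specific kinase MuSK, and AW011738 had log2 fold changes of 0.78 ± 0.14 and 1.08 ± 0.18.

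At the other end, Rgs2, which shortens signalling from Gq-coupled receptors, stood at 6.10 ± 1.24 CPM in the libraries labelled KO-TAC against 15.6 ± 2.67 CPM in WT-TAC (log2 −1.35 ± 0.21). Adra1b, the alpha-1B adrenergic receptor, stood at 12.3 ± 1.49 against 22.5 ± 5.10 CPM (log2 −0.87 ± 0.19). Prcp, a carboxypeptidase that can cleave angiotensin II, had a log2 fold change of −0.78 ± 0.16. Arhgap18, a Rho GTPase-activating protein, had −0.67 ± 0.13, and the tetraspanin gene Tspan2 had −0.88 ± 0.19. Lrrc15, a membrane protein of activated fibroblasts, had −0.98 ± 0.22. The rule that named these 12 genes required that the libraries of the groups did not overlap.

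Over all 17742 genes, 0 passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest adjusted p being 0.9998. At an unadjusted p under 0.05 there were 712 genes, 421 of them higher and 291 lower in the libraries labelled KO-TAC. This is less than a share of 0.05 of the genes tested, which chance alone gives on average, so these 712 are no sign of a difference. Limma voom called 0 genes (1042 at an unadjusted p under 0.05), and DESeq2 called 53, of which 39 were higher and 14 lower (915 unadjusted). All 12 genes named above were among the DESeq2 calls, with DESeq2 adjusted p from 3.39e-05 for Myh7 to 0.0442 for Adra1b. The 12 were picked by small edgeR p from the same counts, so this overlap is no independent support. Groups did not overlap for 8.94% of genes, where chance gives 10%. Without KO-TAC 1 the edgeR test called 19 genes, all higher.

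The STAT1 and interferon list had the smallest p of all lists in limma's camera test with the preset correlation (adjusted p = 2.26e-19), and was not called with an estimated one (adjusted p = 0.779 with an estimated correlation). All 39 members tested were higher by value in the libraries labelled KO-TAC, with a median fold of 2.04 (log2 1.03). When adjusted over the list alone, 29 of them rose past 0.05 in the edgeR test, and 0 did so over all genes tested. B2m, the light chain of MHC class I, stood at 366 ± 74.0 against 199.7 ± 21.8 CPM (log2 0.87 ± 0.19), and the class I heavy chain gene H2-K1 at 271 ± 58.9 against 161 ± 7.83 CPM (log2 0.75 ± 0.18). Rtp4 and Xaf1, both induced by interferon, had log2 fold changes of 1.01 ± 0.26 and 1.22 ± 0.31. Stat1, the transcription factor of the interferon response, had a log2 fold change of 1.58 ± 0.49, from 47.4, 156 and 211 CPM in KO-TAC 1 to 3 and 39.0, 57.2 and 42.3 CPM in WT-TAC 1 to 3. Irf7, a transcription factor that drives interferon genes, was chosen after its values were seen and stood at 35.4, 100.7 and 61.4 against 21.9, 30.3 and 17.9 CPM.

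The interferon genes were high mainly in KO-TAC 2 and KO-TAC 3. The list mean relative to WT-TAC was 0.14, 1.49 and 1.05 (log2) in KO-TAC 1 to 3 and −0.14, 0.14 and 0.00 in WT-TAC 1 to 3. B2m and H2-K1 were above every WT-TAC library in all 3 libraries labelled KO-TAC. Macrophage and myeloid markers, whose cells express many of these genes, had a median log2 fold change of −0.37 that rested on WT-TAC 3 (median −0.02 without it). Their list mean was −0.60, −0.21 and −0.19 in KO-TAC 1 to 3, and −0.18, −0.55 and 0.73 in WT-TAC 1 to 3. Within KO-TAC both lists were thus lowest in KO-TAC 1. Lymphocyte markers had a median of 0.0017. Without KO-TAC 2 the number of members past 0.05 over the list alone was 2, and without KO-TAC 3 or any 1 of the 3 WT-TAC libraries it was 0.

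**Figure D1:**
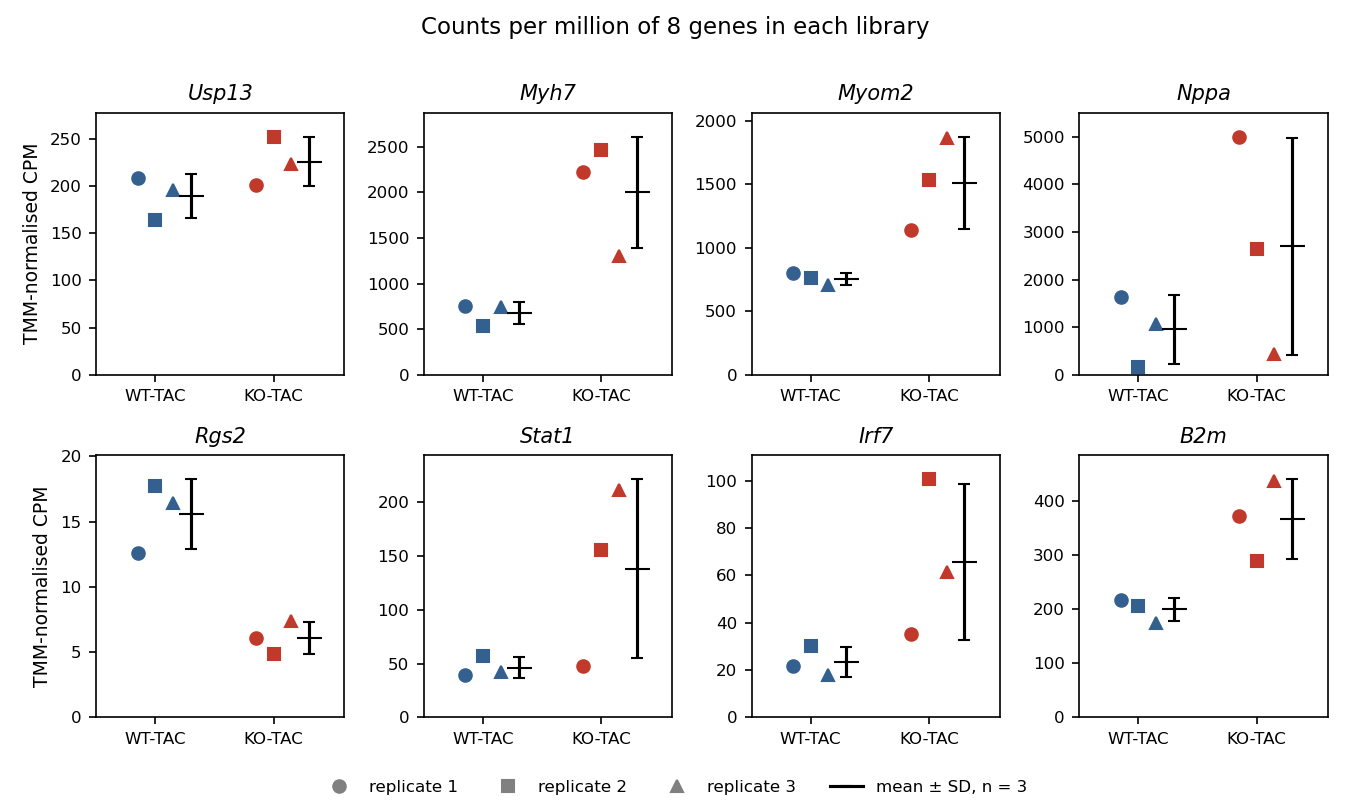
TMM-normalised CPM (vertical axes, linear from 0) of Usp13, Myh7, Myom2, Nppa, Rgs2, Stat1, Irf7 and B2m in each of the 3 WT-TAC (blue) and 3 KO-TAC (red) libraries, with the marker shape giving the replicate and the black bar the mean ± SD. Usp13 overlaps between the groups, Myh7, Myom2, Rgs2, Irf7 and B2m do not, and Stat1 in KO-TAC 1 (47.4 CPM) lies within the WT-TAC range.

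Genes of the hypertrophy and fetal program were called higher as a list in the libraries labelled KO-TAC with the preset correlation of 0.01 (limma camera adjusted p = 1.14e-05). They were not called with the estimated correlation of 0.68 (adjusted p = 0.779). Of 24 members 21 were higher by value, the median fold was 1.86 (log2 0.90), and only Myh7 rose past 0.05 when adjusted over the list alone (edgeR, adjusted p = 0.0134). Nppb, the gene of brain natriuretic peptide, stood at 364 ± 168 against 176 ± 86.6 CPM (log2 1.05 ± 0.43). Synpo2l and Xirp2, genes of actin-binding proteins, had log2 fold changes of 1.07 ± 0.44 and 1.43 ± 0.62. Nppa, the gene of atrial natriuretic peptide, ranged from 439 to 5004 CPM in KO-TAC and from 169.5 to 1624 CPM in WT-TAC, a fitted fold of 2.83 that did not pass. Its log2 fold change was 0.70 without KO-TAC 1 and 2.13 without WT-TAC 1, and that of Nppb 0.60 and 1.498 in the same fits. The log2 fold changes of Acta1, skeletal alpha-actin, and of the growth factor gene Ccn2 were 1.29 ± 0.85 and 1.31 ± 0.66, and neither passed. Leaving out single libraries gave 0.78 (without WT-TAC 2) to 2.62 (without WT-TAC 1) for Acta1 and 0.78 (without KO-TAC 1) to 1.997 (without WT-TAC 3) for Ccn2.

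Libraries of both groups spread widely along this program. The unadjusted camera p was 5.98e-07 for the groups as labelled. Of the 9 groupings that mix the labels, 7 gave a larger camera p, from 9.56e-06 to 0.675, and the others a smaller one, 3.58e-12 for KO-TAC 1, KO-TAC 2 and WT-TAC 1 against the rest, and 1.16e-09 for KO-TAC 1, KO-TAC 2 and WT-TAC 3 against the rest. The list mean relative to WT-TAC was 1.61, 1.00 and −0.14 (log2) in KO-TAC 1 to 3 and 0.45, −0.96 and 0.51 in WT-TAC 1 to 3. Without KO-TAC 1 the median log2 fold change was 0.42 and the camera adjusted p 0.0657. Myh7 no longer passed over the list alone without KO-TAC 1 (edgeR adjusted p = 0.0531), KO-TAC 2 (0.0652), WT-TAC 1 (0.0676) or WT-TAC 2 (0.0611), with log2 fold changes of 1.38 or more in each case.

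Sarcomere and contractile genes were slightly higher in the libraries labelled KO-TAC, 19 of 24 by value, with a median log2 fold change of 0.19. The limma camera adjusted p was 0.00166 with the preset correlation and 0.779 with the estimated one of 0.111. Myom2, an M-band protein that crosslinks myosin, rose past 0.05 over the list alone and stood at 1511 ± 365 against 755 ± 45.1 CPM (log2 1.00 ± 0.21). Myom2 kept that call only without KO-TAC 1 (edgeR adjusted p = 0.0105 over the list alone), and leaving out any other library gave 0.12 to 0.179. Its log2 fold change stayed between 0.82 and 1.04 in the fits that lost the call. Mybpc3, cardiac myosin-binding protein C, and Xirp1 had log2 fold changes of 0.40 ± 0.20 and 0.43 ± 0.16. The main adult myosin gene Myh6 was nearly equal at 19420 ± 6313 and 18120 ± 2259 CPM. Without KO-TAC 3 or WT-TAC 3 the sarcomere list was not called (camera adjusted p = 0.0634 and 0.154).

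Calcium handling and ion channel genes did not pass as a list (median log2 −0.13, limma camera adjusted p = 0.0695, and 0.0174 without KO-TAC 3). Counting that fit, 2 of 15 alternative settings with the preset correlation called the list lower. Kcnj2, the inward rectifier potassium channel Kir2.1, stood at 16.9 ± 2.76 CPM in the libraries labelled KO-TAC against 25.9 ± 1.33 CPM in WT-TAC (log2 −0.62 ± 0.14), and Kcnd2, another potassium channel, had −0.51 ± 0.22. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had −0.29 ± 0.26, and −0.07 without KO-TAC 1. None of the 30 passed over the list alone. The atrial and conduction list (median −0.01, adjusted p = 0.986) and the skeletal muscle list (median −0.02 and mean 0.03, adjusted p = 0.642) did not pass the camera test of limma.

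Fatty acid oxidation and uptake genes were called lower as a list in the libraries labelled KO-TAC with the preset correlation (limma camera adjusted p = 0.0408). They were not called with the estimated one of 0.61 (adjusted p = 0.899). The call was also lost without KO-TAC 1 (adjusted p = 0.986), KO-TAC 2 (0.236) or WT-TAC 2 (0.776, median 0.07). Of 38 members 30 were lower by value, with a median log2 fold change of −0.13, and 0 passed over the list alone. Ucp3, a mitochondrial carrier induced by fatty acids, stood at 10.5 ± 4.36 against 33.5 ± 16.7 CPM (log2 −1.67 ± 0.42). Plin5, a lipid droplet coat protein, and Cpt1a, a carnitine palmitoyltransferase, had −0.56 ± 0.19 and −0.43 ± 0.17.

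Nuclear genes of oxidative phosphorylation (median log2 −0.13, 49 of 51 lower by value) and the mitochondrial genome (median −0.13, 15 of 15 lower) did not pass limma's camera test, with adjusted p of 0.0695 and 0.117. Both were called lower without KO-TAC 3 (camera adjusted p = 4.39e-05 and 0.00821) or WT-TAC 3 (7.42e-09 and 2.14e-06). Counting these fits, 4 of 15 and 3 of 14 alternative settings with the preset correlation called them lower. Sdhc, a subunit of succinate dehydrogenase, had −0.27 ± 0.20, and the mitochondrial 12S ribosomal RNA gene mt-Rnr1 had −0.44 ± 0.40. Glycolysis and glucose use genes had a median of 0.06 (camera adjusted p = 0.138). Among them Pfkfb2, which makes an activator of phosphofructokinase, had 0.57 ± 0.21, and Gapdh stood at 254 ± 56.2 CPM in the libraries labelled KO-TAC against 113 ± 87.3 CPM in WT-TAC. The WT-TAC mean of Gapdh depends on WT-TAC 1, with 213, 70.5 and 54.5 CPM in WT-TAC 1 to 3.

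Among genes of protein turnover, ribosomal proteins were lower and proteasome and heat shock genes higher in the libraries labelled KO-TAC, each by little (limma camera adjusted p = 7.45e-05, 0.0236 and 0.00961). None was called with its estimated correlation of 0.792, 0.55 and 0.217 (adjusted p = 0.899, 0.899 and 0.779). Over the list alone 0 members of the 3 lists passed. Ribosomal proteins were not called without KO-TAC 2 (camera adjusted p = 0.539), the proteasome list without KO-TAC 1 (0.227), KO-TAC 3 (0.282) or WT-TAC 3 (0.885, median −0.0048), and the heat shock list without KO-TAC 1 (0.33) or WT-TAC 3 (0.259). Cytosolic ribosomal protein genes had a median log2 fold change of −0.17 with 43 of 49 lower by value, Rps2 (−0.39 ± 0.20) having the smallest p. Proteasome genes had a median of 0.10 with 25 of 31 higher, and heat shock chaperones a median of 0.17 with 20 of 24 higher. The inducible chaperone genes Hspa1b and Hspa1a had 1.53 ± 0.55 and 1.55 ± 0.58, with 23.0 and 25.5 CPM in KO-TAC 1 and at most 7.60 CPM in any other library.

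Genes tied to the ubiquitin system did not pass as lists. The list of ubiquitin and autophagy partners of USP13 had a median log2 fold change of 0.02 (limma camera adjusted p = 0.377), in which Sqstm1, the autophagy receptor p62, stood at 509 ± 110 CPM in the libraries labelled KO-TAC against 336 ± 55.3 CPM in WT-TAC (log2 0.60 ± 0.21). Deubiquitinase relatives had a median of 0.05 and a mean of 0.09 (camera adjusted p = 0.107, and 0.355 with fry), and Usp28 among them had 0.45 ± 0.14. Their list mean was 0.09, 0.10 and 0.05 in KO-TAC 1 to 3 and 0.01, −0.03 and 0.03 in WT-TAC 1 to 3, without overlap. Of 15 alternative settings with the preset correlation, 1 called the deubiquitinase list higher (camera adjusted p = 0.0493). The ER stress and unfolded protein response list had a median of 0.01 (adjusted p = 0.781). Ppp1r15a, which directs dephosphorylation of eIF2-alpha, was its only member past 0.05 over the list alone, higher in KO-TAC at 32.6 ± 1.39 against 21.3 ± 2.53 CPM (log2 0.62 ± 0.13). That call held only without WT-TAC 1 (edgeR adjusted p = 0.0491 over the list alone), and leaving out any other library gave 0.0782 to 0.208. The log2 fold change of Ppp1r15a stayed between 0.54 and 0.65 in the fits that lost the call. The chaperone Hspa5 had −0.31 ± 0.15.

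Macrophage and inflammatory genes were called lower as lists in the libraries labelled KO-TAC with the preset correlation (limma camera adjusted p = 0.0236 and 0.013). They were not called with the estimated correlations of 0.53 and 0.0874 (adjusted p = 0.899 and 0.779). Without WT-TAC 3 neither was called, with medians of −0.02 for both (adjusted p = 0.998 and 0.246). Without KO-TAC 1 neither was called (0.503 and 0.294), although the medians stayed at −0.28 and −0.35. Macrophage and myeloid markers had a median log2 fold change of −0.37 with 20 of 24 lower by value. Ccr2, the chemokine receptor of recruited monocytes, stood at 3.90 ± 0.85 against 15.7 ± 16.1 CPM, and Lyz2, lysozyme, at 155 ± 29.0 against 321 ± 239 CPM, the high WT-TAC values being 33.9 and 595 CPM in WT-TAC 3. Inflammatory cytokine and NF-kB genes had a median of −0.34 with 23 of 34 lower. The chemokine genes Ccl11, Ccl7 and Cxcl12 had −2.32 ± 0.60, −0.92 ± 0.29 and −0.42 ± 0.15, while the prostaglandin synthase gene Ptgs2 had 0.97 ± 0.38. No member of either list passed over the list alone.

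Neutrophil markers had a median log2 fold change of −0.25 in the libraries labelled KO-TAC (limma camera adjusted p = 0.624), Csf3r among them −0.82 ± 0.52, and were called lower without KO-TAC 3 (0.0322) or WT-TAC 2 (0.0231). Lymphocyte markers had a median of 0.0017 and a mean of 0.02 while the camera statistic was negative (adjusted p = 0.732), and their members went both ways, with Thy1 at −0.79 ± 0.30 and the granzyme gene Gzmb at 2.42 ± 0.97 on under 1 CPM.

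Extracellular matrix genes did not pass as a list and spread widely within both groups. The fibrillar matrix list had a median log2 fold change of −0.0022 and a mean of 0.14 over 46 genes (limma camera, adjusted p = 0.732). Its list mean was 0.86, 0.56 and −0.96 in the libraries labelled KO-TAC 1 to 3, and 0.16 and 0.84 in WT-TAC 1 and WT-TAC 3, with WT-TAC 2 the lowest of all 6. Col1a1 and Col3a1, the main fibrillar collagens, had −0.65 ± 0.84 and −0.83 ± 0.80, and Postn, a matrix protein of activated fibroblasts, had 0.83 ± 1.15. Without WT-TAC 3 the values were 0.54 for Col1a1, 0.22 for Col3a1 and 1.88 for Postn, and Postn had 0.20 without KO-TAC 1. Leaving out 1 library produced calls of the matrix list in opposite directions, higher without KO-TAC 3 (camera adjusted p = 0.000134, median 0.32) or WT-TAC 3 (0.0154, median 0.54) and lower without WT-TAC 2 (0.00798, median −0.17). Fibroblast markers had a median of 0.0018 and a mean of −0.07 (adjusted p = 0.642), although Dpt, dermatopontin, had −0.54 ± 0.14.

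Markers of other cell types did not pass as lists. Endothelial markers had a median log2 fold change of −0.02 (limma camera, adjusted p = 0.642), with Aplnr, the apelin receptor, at −0.73 ± 0.27, and the list was called lower without WT-TAC 3 (adjusted p = 0.0154). Mural markers had a median of −0.02 and a mean of −0.12 (adjusted p = 0.338, and 0.355 with fry). Their list mean was −0.08, −0.16 and −0.19 in KO-TAC 1 to 3 and 0.03, −0.05 and 0.02 in WT-TAC 1 to 3, without overlap. Acta2, smooth muscle alpha-actin, stood at 79.7 ± 28.5 CPM in the libraries labelled KO-TAC against 169 ± 37.8 CPM in WT-TAC (log2 −1.08 ± 0.28). Adipocyte markers had a median of −0.0033 and a mean of 0.0043 (adjusted p = 0.642), and mesothelial and epicardial markers −0.13 (0.642). Schwann and neural markers had a median of −0.49 with 8 of 10 lower (adjusted p = 0.0672), a larger median than that of the macrophage list, and were called lower without KO-TAC 2 (0.00951), KO-TAC 3 (0.00605) or WT-TAC 2 (0.012). Counting these fits, 6 of 15 alternative settings with the preset correlation called the Schwann and neural list lower.

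Erythroid and blood markers were higher as a list, 8 of 9 by value with a median log2 fold change of 1.17. The limma camera adjusted p was 0.00636 with the preset correlation and 0.779 with the estimated one of 0.444. Hbb-bs, a beta-globin gene, stood at 255, 71.0 and 258 CPM in the libraries labelled KO-TAC 1 to 3 and 49.4, 96.6 and 109 CPM in WT-TAC 1 to 3, and Alas2, the erythroid enzyme of heme synthesis, had 1.61 ± 0.60. None passed over the list alone. The call was lost without KO-TAC 1 (adjusted p = 0.17), KO-TAC 3 (0.0634), WT-TAC 1 (0.0599) or WT-TAC 3 (0.0553). The median log2 fold changes in these fits were 0.94, 0.94, 0.86 and 1.36.

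Cell cycle genes were lower as a list in the libraries labelled KO-TAC, 32 of 36 by value with a median log2 fold change of −0.36. The limma camera adjusted p was 0.00636 with the preset correlation and 0.899 with the estimated one of 0.637. Cenpf, a kinetochore protein, had −1.33 ± 0.50, and Mcm7, a subunit of the replicative helicase, −0.38 ± 0.15. None passed over the list alone. The list mean was 0.24, −0.19 and −1.07 in KO-TAC 1 to 3 and −0.11, −0.48 and 0.59 in WT-TAC 1 to 3. Without KO-TAC 3 the median was −0.05 (adjusted p = 0.954) and without WT-TAC 3 it was 0.08 (0.722).

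Signalling and stress lists did not pass limma's camera test. Immediate early genes had a median log2 fold change of 0.16 (adjusted p = 0.0625, and 0.0025 without KO-TAC 3), with Ier5 at 0.65 ± 0.18 and the nuclear receptor gene Nr4a1 at 0.87 ± 0.32. Counting that fit, 4 of 15 alternative settings with the preset correlation called the immediate early list higher. JAK-STAT3 and gp130 genes had a median of 0.10 (0.483), circadian clock genes 0.14 (0.138, and 0.0243 without KO-TAC 1) and glucocorticoid response genes 0.09 (0.406). Within the glucocorticoid list Fkbp5 had 0.75 ± 0.19 and Angptl4, an inhibitor of lipoprotein lipase, −1.51 ± 0.44. Hypoxia and angiogenic genes had a median of −0.03 (0.716), and Apln, which encodes apelin, had −1.15 ± 0.30 in the libraries labelled KO-TAC against WT-TAC. Apoptosis and p53 genes had a median of −0.03 (0.504). Oxidative stress and NRF2 genes had a median of 0.03 and a mean of −0.02 (0.757).

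The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 6 libraries, with log2 fold changes from −0.05 to 0.01. The sex-linked list had a median of −0.04 and a mean of 0.27 (limma camera adjusted p = 0.755), the mean being raised by Xist, at 5.85 CPM in KO-TAC 1 and 0.79 to 1.70 CPM in the other libraries. Of the substrain marker genes, Wdfy1 and Ide had 0.37 ± 0.18 and 0.14 ± 0.11 and Nnt −1.23 ± 1.20, and with 3 genes tested the list had no set test. The counts of Nnt were split over 2 gene IDs in different ways between libraries, and their sum was 329 ± 94.7 CPM in KO-TAC and 436 ± 260.3 CPM in WT-TAC (log2 ratio of the means −0.41). The WT-TAC mean and spread rested on WT-TAC 2, with 47258 summed counts, against 18389 to 28462 in the other libraries. In WT-TAC 2 alone, ENSMUSG00000116207 had 0 counts. Whether that library differs in substrain was not tested.

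Of the 38 lists tested, 11 were called with the preset correlation, 6 higher and 5 lower in the libraries labelled KO-TAC. With an estimated correlation and with fry 0 lists were called. The estimated correlations of the 11 called lists ran from 0.0874 to 0.792, all above the preset of 0.01. The preset camera p-values are too small to the extent that these estimates hold.

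**Figure D2:**
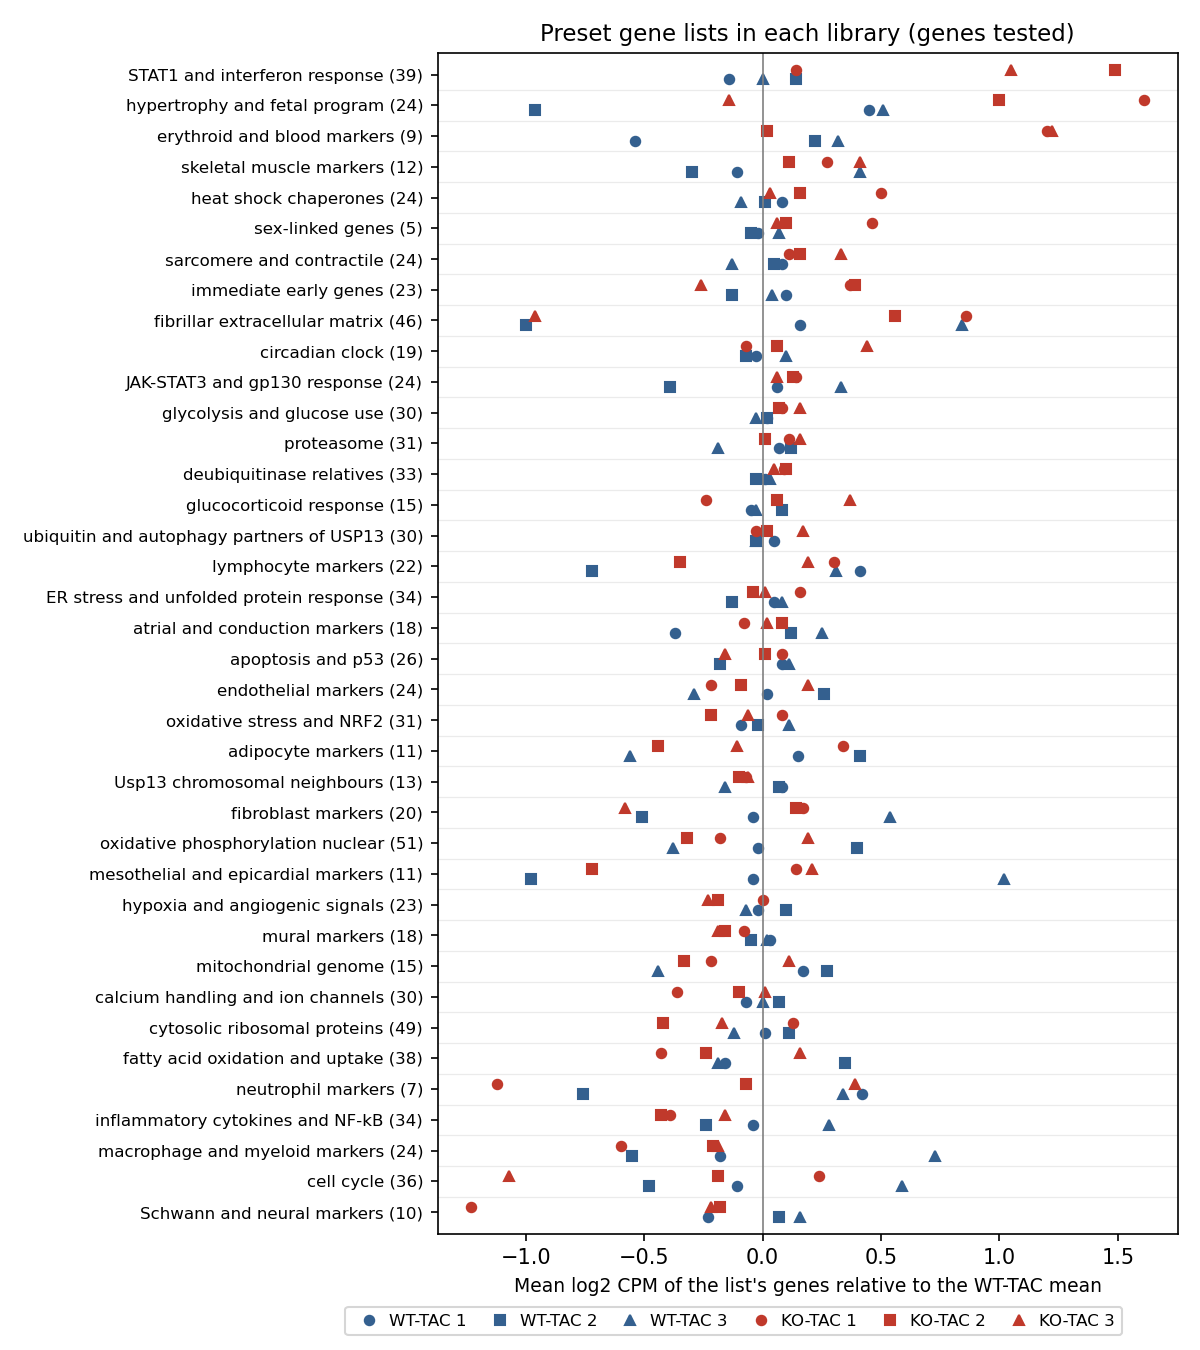
Mean log2 CPM of the genes of each of the 38 preset lists tested, relative to the WT-TAC mean (horizontal axis), in the 3 WT-TAC (blue) and 3 KO-TAC (red) libraries, with the number of genes tested in parentheses and lists ordered by the difference of the group means. KO-TAC 2 and KO-TAC 3 stand at 1.49 and 1.05 for the STAT1 and interferon list, apart from the WT-TAC libraries, while fibrillar extracellular matrix reaches 0.86 in KO-TAC 1 and −0.96 in KO-TAC 3 and overlaps between the groups.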

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

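The fit on protein-coding genes and the count of interferon list members were chosen after seeing the data. The log2 fold change of Usp13 lay between 0.16 and 0.33 in all 15 alternatives and passed in none, its edgeR, DESeq2 or voom adjusted p being 0.818 or more. The count of 0 genes became 53 with DESeq2 (39 higher and 14 lower) and 0 to 19 when single libraries were left out, 19 being without KO-TAC 1 and all higher (0 lower in each). Of these 19, 5 were interferon list members and 3 were also among the DESeq2 calls. The number of lists called ran from 5 (without KO-TAC 1) to 14 (without KO-TAC 3), and was 0 with estimated correlations and 0 with fry. The hypertrophy list had a median from 0.42 to 1.29 when single libraries were left out, and lost its call at 0.90 with an estimated correlation (camera adjusted p = 0.779) and with fry (0.928). The interferon list had medians from 0.71 to 1.301 and was called by camera without each library in turn, and lost its call at 1.03 with an estimated correlation (0.779) and with fry (0.741). Its members past 0.05 over the list alone numbered 0 to 35 when single libraries were left out. The cause was not tested for any of these. Signs turned with voom for Ryr1 (−0.19) and Nnt (0.43). When single libraries were left out, Myh6 ran from −0.11 to 0.34, Col1a1 from −1.12 to 0.54, Col3a1 from −1.28 to 0.22, Krt18 from −0.0098 to 1.68 and Nnt, on 1 of its 2 gene IDs, from −1.79 to 0.46. The fibrillar matrix list was called lower without WT-TAC 2 (−0.1733) and higher without KO-TAC 3 or WT-TAC 3. List medians ran from −0.18 to 0.54 for fibrillar matrix, −0.71 to −0.022 for macrophage markers (where the camera statistic turned), −0.31 to 0.070 for fatty acid oxidation, −0.0048 to 0.15 for the proteasome and −0.64 to 0.079 for the cell cycle. Same-numbered libraries did not deviate together (correlations 0.099, −0.131 and −0.199). The main fit without pairs had been set beforehand, because the labels do not say what the numbers mark. With the replicate number as a block 0 genes, 11 lists and 23 interferon list members were called. The alternatives shifted the median of all genes by no more than 0.0116 in size (log2). In 19 cases an alternative left out a named gene, by the stricter filter or by the genes it removed.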

Other observations

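The genes this part adds, and the tests it sets against explanations, were chosen after the results were seen, while Usp13, Nppa, the lists and the fits without single libraries were fixed beforehand. Beyond the preset list, further genes of MHC class I presentation were above every WT-TAC library in all 3 libraries labelled KO-TAC, KO-TAC 1 included. H2-Q4 stood at 73.9 ± 25.7 against 36.4 ± 3.16 CPM (log2 1.02 ± 0.25), and Psmb10, a subunit of the immunoproteasome, had a log2 fold change of 0.72 ± 0.18. H2-Q5, annotated as a polymorphic pseudogene, had 1.13 ± 0.23, and its reads may belong to near-identical class I genes. Some interferon-induced genes outside MHC class I were also above every WT-TAC library in KO-TAC 1, such as Ifi27l2a (18.2, 26.1 and 16.6 CPM in KO-TAC 1 to 3, at most 11.99 CPM in WT-TAC) and Ube2l6 (13.4, 19.4 and 15.1 CPM, at most 10.7 CPM in WT-TAC). Others were high in KO-TAC 2 and KO-TAC 3 alone. Cd274, which encodes PD-L1, stood at 7.16, 41.1 and 52.8 CPM in KO-TAC 1 to 3 and at 6.42, 9.80 and 8.85 CPM in WT-TAC 1 to 3. Nlrc5, the transactivator of MHC class I genes, stood at 6.72, 36.9 and 32.9 against 5.09, 8.43 and 7.48 CPM. For 3 genes of MHC class II presentation, Cd74, H2-Aa and Ciita, the log2 fold changes were −0.37 ± 0.40, −0.27 ± 0.38 and −0.18 ± 0.42, and no test compared them with class I. Without KO-TAC 1 the 19 genes past the edgeR threshold included the interferon-inducible GTPase genes Iigp1 (2.94 ± 0.22), Irgm1 (2.17 ± 0.17), Igtp (3.17 ± 0.35) and Gbp4 (2.63 ± 0.26), which says how KO-TAC 2 and KO-TAC 3 differ from WT-TAC.

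A few genes of metabolism, blood platelets and signalling also separated the groups by label. Gck, glucokinase, stood at 62.3 ± 10.6 CPM in the libraries labelled KO-TAC against 30.5 ± 9.70 CPM in WT-TAC (log2 1.03 ± 0.23), and Dusp4, a MAP kinase phosphatase, had 1.38 ± 0.28. Apod, apolipoprotein D, had 1.63 ± 0.38 and Col22a1, a collagen of muscle-tendon junctions, 2.92 ± 0.71. The platelet chemokine genes Pf4 and Ppbp had −1.16 ± 0.29 and −1.76 ± 0.44, and Tubb1, the tubulin of platelets, had 0 counts in all 3 libraries labelled KO-TAC and 0.16 to 0.32 CPM in WT-TAC. The platelet genes Itga2b, Clec1b and P2ry12 had −0.32 ± 0.33, −0.34 ± 0.40 and −0.29 ± 0.51. None of these passed the edgeR test over all genes.

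Usp13 was not lower in the libraries labelled KO-TAC, and both tests here were chosen after this was seen. No library had low Usp13, the lowest standing at 0.786 of the median of the other 5. This excludes no exchange of libraries between the groups, because it is not known whether the allele lowers whole-gene counts, so an exchange cannot be told apart. An allele that removes few exons and leaves the transcript counted cannot be told apart from an intact gene, because counts cover the whole gene, and the lower 95% limit of the log2 fold change was −0.107. A deletion in part of the heart's cells, or knockout labels on hearts without the deletion, may also give this pattern and were not tested.

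The interferon list was higher in the libraries labelled KO-TAC, mainly in KO-TAC 2 and KO-TAC 3, and the 3 tests here were chosen after this was seen. The interferon list mean minus the macrophage marker mean was higher in KO-TAC by 1.23 (SE 0.494). With 3 libraries per group this gap is uncertain, and it leans on WT-TAC 3, where the macrophage mean was 0.73. Macrophage means in KO-TAC 2 and KO-TAC 3 (−0.21 and −0.19) lay between WT-TAC 2 (−0.55) and WT-TAC 1 (−0.18). These markers therefore do not set KO-TAC 2 and KO-TAC 3 apart as the interferon list does, but a part played by macrophages is not excluded. For lymphocyte markers the interferon mean minus the marker mean was higher by 0.846 (SE 0.723), and a change in lymphocytes cannot be told apart at this spread. An MHC haplotype from another strain or reads shared among class I paralogs would leave other members near 0, yet the 33 members outside MHC class I and antigen processing had a median log2 fold change of 1.12, and 23 of them passed over the list alone. This leaves open such an effect on the class I genes themselves. In KO-TAC 1, H2-K1 (252 CPM) was above every WT-TAC library (at most 168 CPM), while Stat1 (47.4 CPM) was not. The genotype given by the labels, or an exposure of some animals such as an infection, may account for the pattern as a hypothesis, and neither was tested.

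Nppa ranged from 169.5 to 5004 CPM, with the highest level in KO-TAC 1, and the test here was chosen after this was seen. Atrial tissue in some samples may raise Nppa. Myl7, the abundant atrial myosin light chain, reached at most 1.67 CPM in any library and had 0 counts in KO-TAC 1. This argues against that source as far as the Myl7 counts can be trusted, since a count of 0 may also reflect how reads were assigned. Myl4, another atrial light chain, stood at 2.70, 1.35 and 3.77 CPM in KO-TAC 1 to 3 and 0.98 to 1.35 CPM in WT-TAC. Both were highest in KO-TAC 3, where Nppa was 439 CPM. Differences in the strength of constriction between animals stay open as a hypothesis and were not tested.

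The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05, and they were compared after the results were seen. EdgeR called 0 genes in the real split and at most 1 in another, and since no split can give fewer than 0, all 10 gave as many by construction and the comparison decides nothing. At an unadjusted p under 0.05 edgeR gave 712 genes in the real split and from 202 to 1998 in the others. DESeq2 called 53 in the real split and up to 412 in another, and 5 splits gave as many. The split with 412 set KO-TAC 1, KO-TAC 2 and WT-TAC 3 against the rest, which points to a structure of the samples across the labels. Those libraries had lower mitochondrially encoded shares (28.1%, 26.5% and 26.1% of counts) than KO-TAC 3, WT-TAC 1 and WT-TAC 2 (30.6%, 32.3% and 33.1%). They also had more genes with a count (22093, 22147 and 22979 against 21575, 21390 and 21418). The cause of this structure was not tested. The number of lists called was 11 in the real split and up to 17 in another, and 5 splits gave as many. Interferon list members past 0.05 over the list alone numbered 29 in the real split and 21 in the highest other, which set KO-TAC 2, KO-TAC 3 and WT-TAC 2 against the rest, and 1 split, the real one, gave as many.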
